A study of Mycosarcoma maydis with 9 samples.

How the data were processed

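RNA of Ustilago maydis strain SG200 was sequenced in 9 libraries, 3 each of axenic yeast-like cells, infected maize leaf at 2 dpi and infected maize leaf at 12 dpi. Per the labels' protocols, 7-day-old seedlings were inoculated with cells grown to an OD600 of 1.0, leaf sections of 10 plants were pooled per infected sample, RNA was extracted with TRIzol and libraries were made from polyadenylated RNA with a stranded kit. The series design text also names a cross of strains FB1 and FB2, which none of the 9 samples represents, so that comparison was not made.

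The authors deposited 1 value per gene and library for 6766 genes, a size-factor scaled signal. The values are not whole, although every value is a whole number of reads divided by 1 factor per library, within 0.01 read for 100% of the values in each library. The factors equal median-of-ratios size factors recomputed from the recovered reads, and the submitters' processing notes name DESeq2 1.10. A second deposited table holds the mean and SD of the same scaled signal per group, equal to those of the first table within 1e-06 for all 6766 genes. The processing notes also name the maize genome build B73 RefGen_v3, while the aligner, the counting tool, the fungal genome build and its annotation are not given in the sources used here. Whether the counting used strand, and how it treated reads shared by near-identical genes, is not stated, so values of overlapping genes and of members of multigene families such as the effector clusters are uncertain to that extent. The plant reads and the total reads per library are not in the deposited tables.

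Of the 6766 gene identifiers, 6762 matched locus tags of a RefSeq gene table of assembly Umaydis521_2.0, which was used for 15 gene symbols other than the locus tag and for which genes neighbour each other. Other gene names (such as pep1) are published locus designations that were fixed in 13 lists of 136 members, 125 of them in the table, and they do not come from the deposited tables. The reference table holds no product descriptions or sequences. For that reason lists defined by product text, a list of secreted-like proteins, and the alternative that leaves out conserved genes open to maize reads were not run.

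The test fixed before the data were examined was the edgeR quasi-likelihood test on raw counts. The deposited values turned out to be scaled, and the main test was changed to limma 3.58.1 in R 4.3.3. It was run with trend and robust options on log2(value + 12). The recovered whole reads allowed the edgeR test as well, so the scaling did not force this change. The pseudocount of 12 is the value of 1 read in the shallowest library. Genes with a mean scaled value of at least 20 over the 9 libraries were tested, which left 5377, with all 9 libraries in 1 fit of 3 group means and no covariate. Adjusted p values are Benjamini-Hochberg values, with a threshold of 0.05. The edgeR test was run as an alternative on the recovered reads, where it called 2457, 2515 and 889 of 4516 genes for 2 dpi against axenic, 12 dpi against axenic and 12 against 2 dpi.

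Genes named in the text were taken by a rule fixed beforehand. Up to 4 members per list and comparison with the largest changes past the threshold, and any member that did not pass, could be named, as could every member of the effector and regulator lists, and the 4 largest rises and 4 largest falls among genes whose 3 libraries of 1 group all lay above the 3 of the other and whose higher group had a mean CPM of at least 10. The part of the rule for annotated products could not be applied. Further members named as examples of a time course, and the genes with reference symbols in the closing section, were chosen after the data were examined.

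Gene lists were tested with camera at a preset correlation of 0.01 on log2(value + 12), in place of log CPM, and again with an estimated correlation and with fry, which tests whether a list moves one way and does not compare it with other genes. Of 13 lists 12 had at least 2 tested members, which gave 36 tests adjusted together, of which 21 passed with the preset correlation and 9 with the estimated one. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within each list. A fold against a group with 0 reads is a lower bound against 3 reads over the group, from summed reads over summed size factors, and a fold against a group with 1 to 3 reads is not given. These floors cover counting error only. The overlap of stages was set against 50 simulations of unchanged groups that share the axenic libraries, and depth was compared with exact permutation tests.

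Calls per gene by limma, limma with a weight per group and edgeR were tested on simulated counts. These were drawn from means, depths and spread of the libraries, with 200 genes changed in each of 10 runs per comparison. DESeq2, the list tests, the permutation tests and the tests of neighbouring genes were not tested in this way. For 2 dpi against axenic, over a mean of 5332 tested genes, limma recovered 13.7%, 74.8% and 89.2% of 2-fold, 4-fold and 8-fold changes with 1.9% false calls. For 12 dpi against axenic, over 5333 genes, it recovered 18.1%, 76.0% and 86.2% with 4.1% false calls. For 12 against 2 dpi, over 4936 genes, it recovered 21.3%, 71.9% and 83.8% with 9.9% false calls, more than the threshold states. The 200 changed genes were a smaller share than the 23.9% called in the real libraries, and the false share depends on that share. Calls of that comparison may therefore hold more false ones than the threshold states, by an amount these runs do not give. No recovered gene had the wrong sign.

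The alternatives fixed before the data were examined were edgeR 4.0.16 with size factors or upper-quartile factors, DESeq2 1.42.0, no filter, fits of the 2 groups compared, the replicate number as a block, a pseudocount of 1, libraries thinned to the smallest, a test against a 2-fold change and leaving out each library in turn. Values rescaled with TMM, a weight per group, and the overlap and the folds without each library were added after the data were examined. So was a shuffle of neighbours among genes with as many wide gaps. The edgeR test with TMM factors was the test fixed beforehand, and its place as an alternative was decided afterwards.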

Results

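Transcripts of the corn smut fungus Ustilago maydis were measured by stranded sequencing of polyadenylated RNA in 9 libraries of strain SG200, which infects maize without a mating partner. The libraries formed 3 groups of 3. One group came from yeast-like cells in axenic culture, and the others came from infected maize leaf sections at 2 and 12 days post infection (dpi), with 10 plants pooled per infected library. The axenic libraries held 15644841, 16218728 and 12432987 fungal gene reads. The libraries held 164466, 183018 and 602852 fungal reads at 2 dpi, and 172440, 64438 and 114611 at 12 dpi. Axenic depth was 46.6 times that at 2 dpi and 126.0 times that at 12 dpi, each with p = 0.1 in a 2-sided exact permutation test, the smallest value that 3 libraries against 3 allow. Depth at 2 dpi was 2.70 times that at 12 dpi, with p = 0.2 in the same exact test.

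Expression values below are read counts scaled by 1 size factor per library, given as mean ± SD with n = 3 libraries per group. One read corresponded to a scaled value of 0.0405 to 0.0531 in the axenic libraries, 1.27 to 4.52 at 2 dpi and 4.16 to 12.0 at 12 dpi. The median gene had 697.5 to 961 reads in an axenic library, 9 to 32 at 2 dpi and 3 to 10 at 12 dpi. The count of 3 reads, up to which a gene with 0 reads in a library may lie, corresponded to 12.5 to 35.9 scaled units at 12 dpi, so weakly expressed genes were not measurable in the infected leaf. Log2 changes are differences of log2(value + 12) with their standard error (SE), which damps the change of weakly expressed genes, and folds are ratios of group means. Of 6766 genes, 5377 passed the filter and were tested. The first principal component held 69.8% of the variance and separated all axenic from all infected libraries, and the second held 16.1% and separated 2 from 12 dpi.

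The comparison of 2 dpi with axenic culture asked which fungal genes change early in the colonised leaf. Characterised effectors, secreted proteins that act on the host, rose at 2 dpi from values near 0. The repetitive effector rsp3 (UMAG_03274) went from 0.224 ± 0.158 to 19548 ± 1155, a log2 change of 10.64 ± 0.15. The cell-to-cell extension effector erc1 (UMAG_01829, named afu1 in the reference table) went from 0.439 ± 0.0799 to 10328 ± 471, and the chorismate mutase cmu1 (UMAG_05731) from 3.35 ± 1.17 to 4474 ± 618, which was 1340-fold. The peroxidase inhibitor pep1 (UMAG_01987) reached 678 ± 41.7, a 5590-fold rise, and the penetration effector stp1 (UMAG_02475) reached 1446 ± 34.2. The protease inhibitor pit2 (UMAG_01375), with 2 reads over the axenic group, reached 2669 ± 358. The effector tin2 (UMAG_05302), with 0 axenic reads, reached 67.2 ± 15.0, at least 1380-fold higher than the level of 3 reads over the axenic group. All 12 effectors rose over all genes tested, and 12 rose when adjusted over the list alone.

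Virulence regulators rose as well, with 12 of 13 tested past the threshold and 12 adjusted over the list alone. The membrane protein gene pit1 (UMAG_01374) reached 2783 ± 477 from 2 axenic reads. The homeodomain factor hdp2 (UMAG_04928) rose 1550-fold to 556 ± 58.0, the development regulator clp1 (UMAG_02438) 1190-fold to 247 ± 22.7, and the mating type genes bE (UMAG_12052) and bW (UMAG_00578) 795-fold and 244-fold (bW 452-fold without axenic replicate 3). The spore formation regulator ros1 (UMAG_05853) did not pass, at 43.1 ± 5.03 in culture and 30.9 ± 5.89 at 2 dpi (adjusted p = 0.328). The listed genes rbf1 (UMAG_03172) and rop1 (UMAG_12033) lay under the expression filter.

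Genes of known effector clusters, given by locus ranges, rose in the same comparison. In the 19A range, 14 of 16 tested genes rose, or 16 adjusted over the list alone, and UMAG_05318 went from 0 axenic reads to 736 ± 162. In the 2A, 6A and 9A ranges, 20 of 22 rose, or 21 adjusted over the list alone, led by UMAG_03748 at 1763 ± 182 and UMAG_02540 at 966 ± 100.3. Limma did not call UMAG_05295 and UMAG_05313 in the 19A range or UMAG_03746 and UMAG_03753 in the others. By edgeR each rose (adjusted p = 2.34e-06, 0.0296, 0.000108 and 0.000977), as by DESeq2 (1.03e-13, 0.0223, 3.19e-11 and 4.37e-06). At 2 dpi UMAG_03746 had reads in replicate 3 only. All 4 genes of the maize-induced mig2 range rose, and all 4 when adjusted over the list alone, with UMAG_06181 at 3037 ± 429. Camera tests against the other genes, adjusted over 36 tests, placed the lists above the rest at adjusted p = 1.78e-16 for effectors, 1.11e-09 for regulators, 6.02e-10 for 19A, 3.07e-18 for 2A, 6A and 9A, and 8.21e-07 for mig2. The mig2 call was lost, with adjusted p = 0.0581 with an estimated correlation, and the other 4 held at 0.0367. The effector list shares tin2 with the 19A range and jsi1 (UMAG_01236) with the 2A, 6A and 9A ranges, so these tests are not independent of each other.

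**Figure D1:**
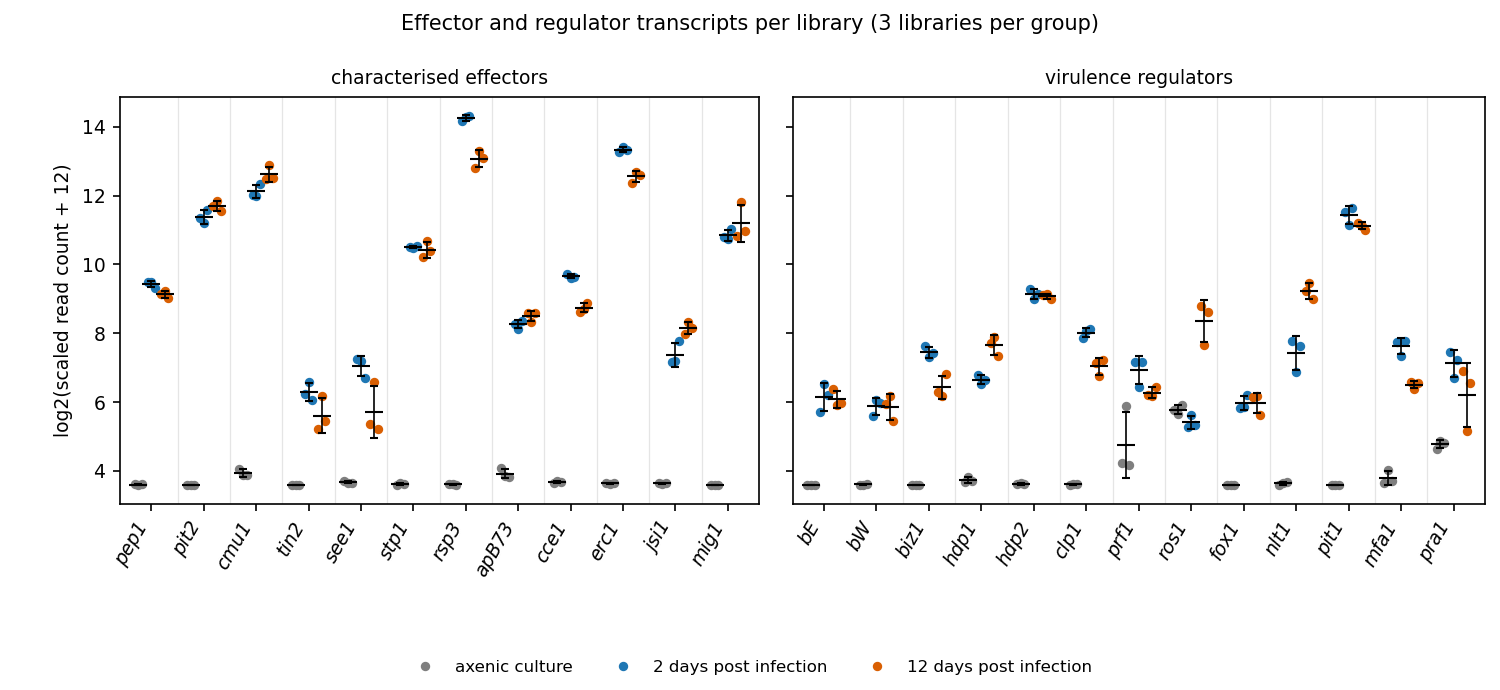
Values of log2(scaled read count + 12) for the tested members of the effector and regulator lists, with 1 dot per library, black bars at the mean ± SD and 3 libraries per group. All 12 effectors lay higher in both infected groups than in axenic cells, while ros1 rose at 12 dpi alone, to 336 ± 127.

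Some nutrient and iron genes changed at 2 dpi. The sucrose transporter srt1 (UMAG_02374) rose 21.1-fold to 465 ± 30.5 and the ammonium permease ump2 (UMAG_05889) 413-fold to 223 ± 17.1, while the nitrogen regulator nit2 (UMAG_10417) went from 68.6 ± 18.5 to 87.0 ± 14.7 and did not pass. These were 2 of 3 tested nutrient genes, and 2 adjusted over the list alone (camera adjusted p = 0.006, and adjusted p = 0.0581 with an estimated correlation). In the iron list, UMAG_01435 rose 21.5-fold and sid2 (UMAG_10189), a ferrichrome synthetase, 2.66-fold, while sid1 (UMAG_10188), the first enzyme of siderophore synthesis, fell to 0.187 of its axenic mean. That made 2 risen and 1 fallen of 5 tested, or 3 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.323). UMAG_01436 did not pass in the main limma fit but rose by edgeR (adjusted p = 0.00193) and by DESeq2 (0.000456). Limma also called its rise with a pseudocount of 1 (adjusted p = 0.00896), with a weight per group (0.0176) and without 12 dpi replicate 2 (0.0414). The other 7 of the 12 listed iron genes lay under the filter and were not tested, among them UMAG_01432, with 31.9 ± 11.4 in culture, 3 reads at 2 dpi and 0 reads at 12 dpi, UMAG_01431, with 18.3 ± 9.96, 4 reads and 1 read, and UMAG_01433, with 10.7 ± 4.11, 0 reads and 3 reads. Among 8 chitin synthases, 4 rose, including chs7 (UMAG_05480) at 2.55-fold, and chs3 (UMAG_10120) fell to 0.231 of its axenic mean, with the same counts adjusted over the list alone (camera adjusted p = 0.141). The call of sid2 was lost without axenic replicate 3 (adjusted p = 0.065) or 2 dpi replicate 1 (0.075), within a range of 0.00302 to 0.075 over 20 alternatives.

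The call of the itaconate cluster, which makes an organic acid, depended on the tool at 2 dpi, and for its gene mtt1 also on the pseudocount. With a pseudocount of 1 limma called mtt1 (adjusted p = 0.0175). By limma with the main pseudocount 2 of 5 tested genes rose, and 2 adjusted over the list alone, whereas all 5 rose by edgeR and by DESeq2. The 3 others were mtt1 (UMAG_05079), ria1 (UMAG_05080) and adi1 (UMAG_11778), with 6, 21 and 4 reads over the 2 dpi group, at adjusted p = 0.000849, 0.00165 and 0.000845 by edgeR, 2.36e-08, 1.27e-05 and 7.13e-07 by DESeq2, and 0.385, 0.185 and 0.494 by limma. The limma calls were cyp3 (UMAG_05074) at 32.5 ± 11.7 and the aconitate decarboxylase gene tad1 (UMAG_05076) at 51.6 ± 35.4, and tad1 was lost without axenic replicate 1 (adjusted p = 0.0522) or 2 dpi replicate 2 (0.0747, the highest of 20 alternatives, with 0.000156 the lowest). The cyp3 call was lost in thinned libraries (adjusted p = 0.0701). Of 3 tested melanin genes, 1 rose, and 1 adjusted over the list alone, the laccase lac1 (UMAG_05861), from 0.929 ± 0.216 to 565 ± 37.1. Neither tested gene of the mannosylerythritol lipid cluster rose, also when adjusted over the list alone, and none of the 9 genes of the ustilagic acid range in the table reached the filter at any stage. Camera adjusted p was 0.14, 0.144 and 0.985 for itaconate, melanin and the lipid cluster, whose median log2 change was 0.02 although camera placed it below the other genes.

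Genes used as expression references fell in the leaf. Means of cyclophilin ppi1 (UMAG_03726) went from 2395 ± 98.5 to 1201 ± 194, of gapdh (UMAG_02491) from 3137 ± 321 to 1544 ± 201 and of actin act1 (UMAG_11232) from 1663 ± 135 to 1197 ± 181. All 3 fell over all genes and all 3 adjusted over the list alone, under each of 4 scalings. The act1 call was lost without axenic replicate 2 (adjusted p = 0.0833), axenic replicate 3 (0.0797), 2 dpi replicate 1 (0.121) or 2 dpi replicate 3 (0.0758), in a range of 0.0063 to 0.121. Camera gave adjusted p = 0.0356, adjusted p = 0.253 with an estimated correlation, and 0.0578 without 12 dpi replicate 2.

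Across the genome, 2125 genes, 39.5% of those tested, changed at 2 dpi by limma at an adjusted p threshold of 0.05, with 1070 risen and 1055 fallen. The balance turned in some alternatives, to 1183 risen and 1274 fallen by edgeR with TMM and 1117 and 1368 by edgeR with upper-quartile factors. Of the 2125 limma calls, 396 rose and 148 fell by 4-fold or more on the fitted scale, and 36 risen genes had no axenic read. Besides rsp3 and erc1, the largest rises were UMAG_01820, from 0.328 ± 0.184 to 17364 ± 2096, and UMAG_04422, from 0.374 ± 0.0920 to 9576 ± 1003. The largest falls were UMAG_10186, from 1715 ± 213 to 14.8 ± 7.19, UMAG_02763, from 2115 ± 983 to 21.4 ± 4.43, UMAG_05972, from 5620 ± 2930 to 94.7 ± 35.9, and UMAG_10815, from 1064 ± 257 to 29.7 ± 5.72. In simulated libraries of these depths the test recovered 13.7% of genes changed 2-fold, 74.8% of those changed 4-fold and 89.2% of those changed 8-fold. Those runs changed 200 of about 5332 tested genes, a smaller share than was called here, and the adjusted threshold depends on that share. The recovery of small changes in the real libraries may therefore differ. The called rises and falls had median log2 changes of 1.375 and -1.161. With all libraries thinned to the smallest, 1375 genes passed, and 578 passed a test against a 2-fold change.

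The comparison of 12 dpi with axenic culture asked which genes are changed in the late infection. Effectors stayed far above culture, with all 12 risen and all 12 adjusted over the list alone. Means reached 8677 ± 1497 for rsp3, 6349 ± 1013 for cmu1, 6040 ± 672 for erc1, 3300 ± 323 for pit2 and 548 ± 39.1 for pep1. All 13 tested regulators rose, and 13 adjusted over the list alone. The listed rop1 and rbf1 lay under the filter and were not tested. Scaled values of rop1 were 21.0 to 31.1 in culture and 0 to 12.0 at 12 dpi, those of rbf1 1.05 to 1.91 and 0 to 23.9, on few reads in the leaf. Among the tested regulators ros1 rose 7.79-fold to 336 ± 127 and nlt1 (UMAG_04778), a regulator of leaf tumour formation, rose 1290-fold to 592 ± 99.3. The pheromone response factor prf1 (UMAG_02713) was lost with edgeR (adjusted p = 0.161, in a range of 0.000113 to 0.228 over 19 alternatives).

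The itaconate genes were high at this stage, with all 5 tested genes risen and all 5 adjusted over the list alone. The cytochrome P450 gene cyp3 reached 2839 ± 862 from 1.49 ± 0.466, tad1 reached 2464 ± 823 from 13.8 ± 4.03, the mitochondrial transporter mtt1 reached 362 ± 221 from 4 axenic reads, and adi1 reached 167 ± 45.9 from 5 axenic reads. All 3 tested melanin genes rose, and all 3 adjusted over the list alone. Of the 6 listed, pks3 (UMAG_04105), pks4 (UMAG_04097) and pks5 (UMAG_04095) lay under the filter, with few or 0 reads in the leaf, and were not tested. The polyketide synthase genes pks1 (UMAG_06414) and pks2 (UMAG_06418) reached 219 ± 70.3 and 114 ± 33.8, 43.0-fold and 114-fold above culture. Camera gave adjusted p = 4.71e-05 for itaconate and 0.00266 for melanin, against adjusted p = 0.0581 and 0.0564 with an estimated correlation, so neither call held there.

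Some iron and nutrient genes lay above culture at 12 dpi and others did not. The sucrose transporter srt1 rose 35.4-fold to 780 ± 27.9 and ump2 1150-fold to 623 ± 65.4. All 3 tested nutrient genes rose, and 3 adjusted over the list alone (camera adjusted p = 0.00444, and adjusted p = 0.0581 with an estimated correlation). The nit2 rise of 1.70-fold was lost without axenic replicate 1 (adjusted p = 0.166), 12 dpi replicate 2 (0.0998) or 12 dpi replicate 3 (0.0813), in a range of 0.0175 to 0.351. In the iron list 3 of 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0886). UMAG_01436 rose 92.5-fold to 325 ± 53.3, UMAG_01435 57.5-fold and sid2 11.2-fold, while the ferroxidase fer1 (UMAG_00105) fell to 0.214 of its axenic mean (0.0923 without 12 dpi replicate 3) and sid1 did not pass (52.0 ± 15.1 in culture, 42.7 ± 26.9 at 12 dpi, adjusted p = 0.477). In the lipid cluster mmf1 (UMAG_03116), a transporter gene, rose 29.9-fold to 60.8 ± 35.9 and was 1 of 2 tested, also adjusted over the list alone (camera adjusted p = 0.382).

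**Figure D2:**
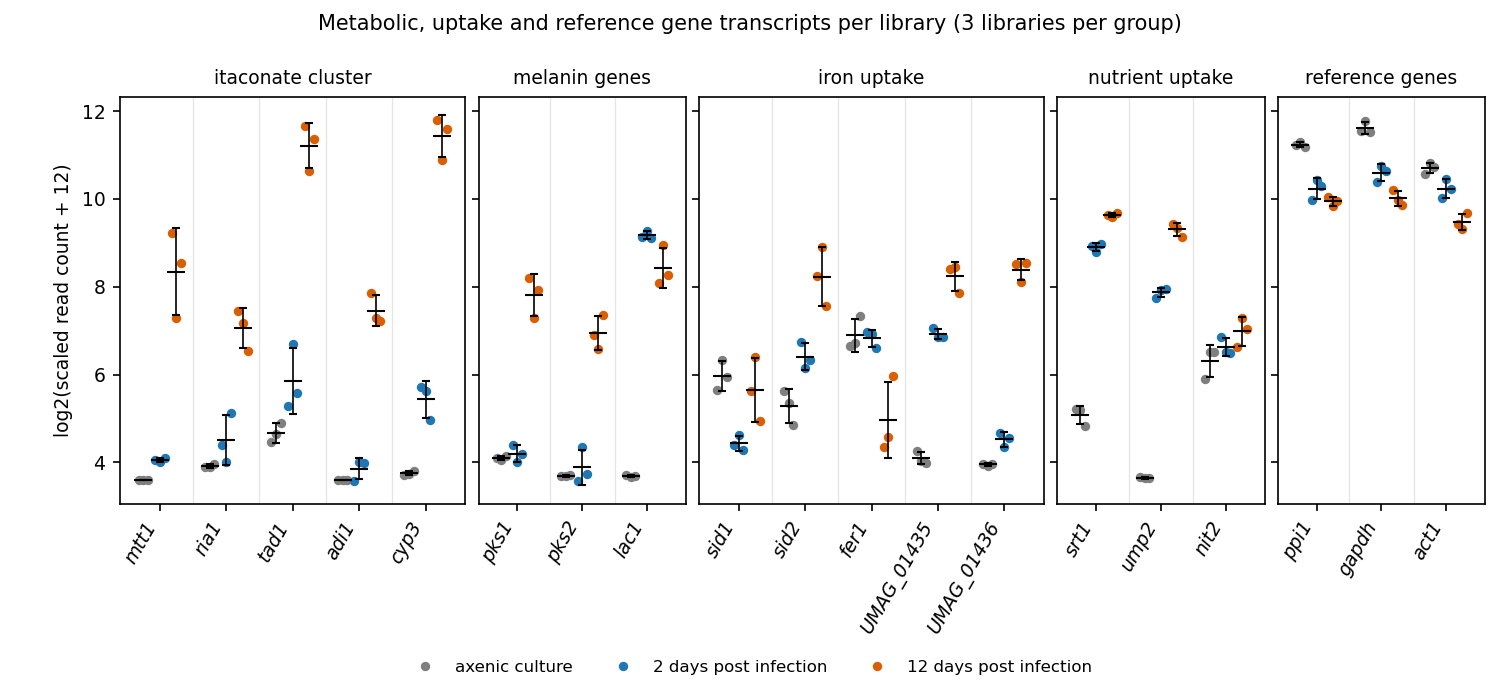
Values of log2(scaled read count + 12) for the tested genes of the itaconate, melanin, iron, nutrient and reference lists, with 1 dot per library, black bars at the mean ± SD and 3 libraries per group. The 5 itaconate genes and pks1 and pks2 were highest at 12 dpi, lac1 was high at both stages, and the 3 reference genes were lower in leaves.

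In the cluster ranges, 14 of 16 tested 19A genes rose, and 14 adjusted over the list alone, with UMAG_05312 at 1440 ± 163 and UMAG_05295 at 1355 ± 61.2. In the 2A, 6A and 9A ranges 21 of 22 rose, and 21 adjusted over the list alone, with UMAG_03749 at 1150 ± 48.8. Of the genes limma did not call, UMAG_05317 and UMAG_03753 rose by edgeR (adjusted p = 0.00188 and 0.0188) and by DESeq2 (6.57e-08 and 0.00442), while UMAG_05313 passed by neither. All 4 mig2 genes rose, and 4 adjusted over the list alone, with UMAG_06179 at 9539 ± 713. Of the chitin synthases 5 rose, including chs7 at 3.61-fold, and chs3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.126). The reference genes ppi1, gapdh and act1 fell to 0.407, 0.327 and 0.421 of their axenic means with the authors' size factors, which was all 3, and all 3 adjusted over the list alone, and all 3 were also lower under 3 other scalings (camera adjusted p = 0.0143, and adjusted p = 0.219 with an estimated correlation). Camera adjusted p was 2.24e-13 for effectors, 3.77e-09 for regulators, 1.86e-09 for 19A, 1.97e-15 for 2A, 6A and 9A and 5.17e-06 for mig2. With an estimated correlation these became adjusted p = 0.0367, 0.0367, 0.0367, 0.047 and 0.0581, so the mig2 call alone among these was lost.

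Across the genome, 2731 genes, 50.8% of those tested, changed at 12 dpi, with 1275 risen and 1456 fallen, of which 508 and 287 did so by 4-fold or more. The balance turned in some alternatives, to 1707 risen and 1341 fallen by DESeq2 and 1277 risen and 1223 fallen by edgeR with size factors. The largest rise was UMAG_03046, with 0 axenic reads and a mean of 34373 ± 961, at least 775000-fold above the level of 3 reads over the axenic group. UMAG_06126 followed, from 0.283 ± 0.183 to 13167 ± 1966, then UMAG_06179 and rsp3. The largest falls were UMAG_10186, to 1 read over the 12 dpi group from 1715 ± 213, UMAG_02763, to 14.9 ± 8.08, UMAG_05972, to 106 ± 21.0, and UMAG_15021, to 3 reads from 753 ± 318. Thinned libraries gave 1807 genes and the test against a 2-fold change gave 921.

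The changes at both stages were set side by side to ask how far the early and late programmes are shared. Of 5377 genes, 851 rose at both stages and 814 fell at both, against 254 and 286 for independent lists of these sizes and 0 in each of 50 simulations of unchanged groups against the same axenic libraries. Unchanged groups give almost no calls, so this 0 does not measure how far the shared controls enlarge the overlap of real changes. Opposite calls were made for 17 genes. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.854 (0.256 simulated) and a covariance of 2.12 (0.025 simulated), a difference in covariance of 2.09. In the simulations the shared axenic libraries gave a covariance of at most 0.028. That argues against replicate noise of the shared controls as the source of most of the covariance. A deviation common to all 3 axenic libraries was not simulated. The 3 axenic libraries cannot be split into parts of at least 2, so part of the excess of shared calls may come from the shared controls. Thinned libraries gave 1033 genes changed alike, against 1665.

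**Figure D3:**
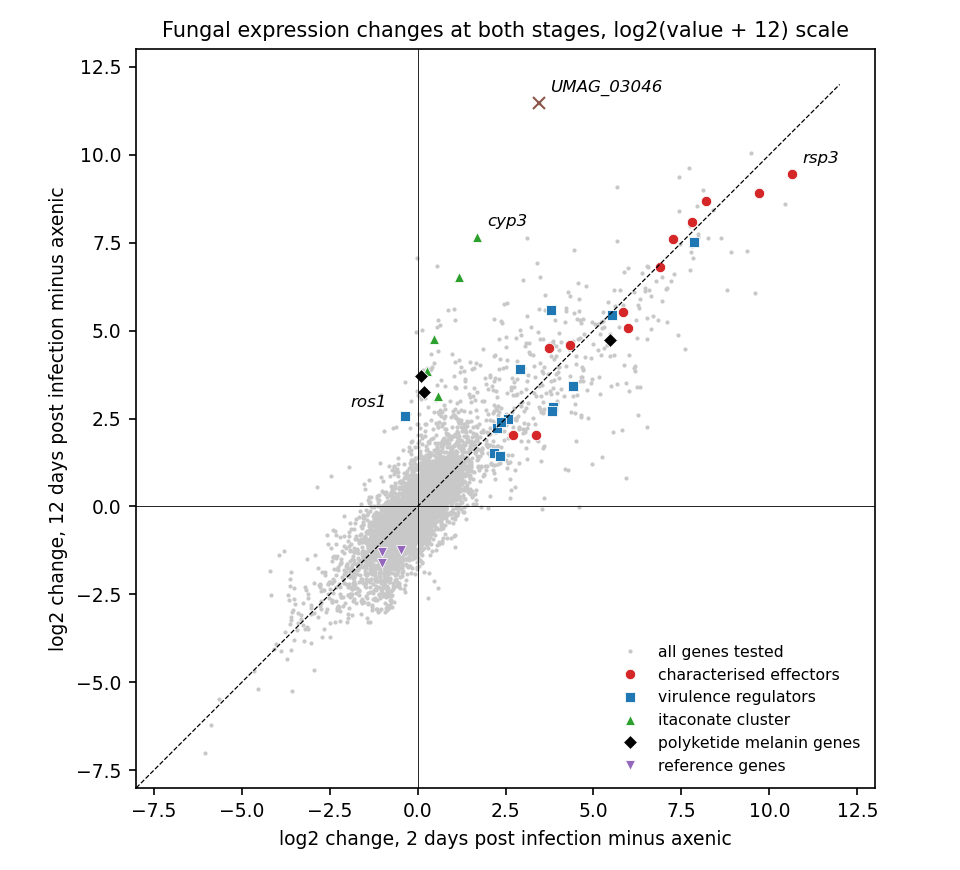
Log2 change at 12 dpi against log2 change at 2 dpi, each minus axenic, with 1 point per tested gene, fixed lists in colour and the dashed line marking equal change. Effectors lie near the line, with rsp3 at 10.64 and 9.46, while cyp3 lies at 1.68 and 7.67, ros1 at -0.36 and 2.58, and UMAG_03046 at 3.46 and 11.48.

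The comparison of 12 with 2 dpi asked which genes distinguish the late from the early infection. All 5 tested itaconate genes were higher at 12 dpi, and all 5 adjusted over the list alone. The P450 gene cyp3 was 87.4-fold higher (log2 change 5.99 ± 0.27), mtt1 78.9-fold, adi1 62.7-fold and tad1 47.7-fold (tad1 78.6-fold without 2 dpi replicate 2). Camera gave adjusted p = 7.43e-09 and held, with adjusted p = 0.0367 with an estimated correlation. The polyketide synthase gene pks1 was 33.6-fold higher and pks2 rose by a log2 change of 3.06 ± 0.32 from 3 reads at 2 dpi, while lac1 fell from 565 ± 37.1 to 344 ± 118, which made 2 melanin genes risen and 1 fallen of 3 tested, also adjusted over the list alone. The melanin list passed camera at adjusted p = 0.0376 but not at adjusted p = 0.12 with an estimated correlation, nor without 12 dpi replicate 2 (0.0767). The fall of lac1 was lost with edgeR (adjusted p = 0.0661, in a range of 0.00215 to 0.288 over 20 alternatives) and without any of the 2 dpi libraries or of 12 dpi replicates 1 and 3 (0.0717 to 0.1).

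Regulators went both ways between the stages, with 3 risen and 3 fallen of 13 tested, and the same counts adjusted over the list alone. The spore formation regulator ros1 rose 10.9-fold, from 30.9 ± 5.89 to 336 ± 127, nlt1 rose 3.57-fold and the homeodomain factor hdp1 (UMAG_12024) 2.17-fold. The zinc finger factor biz1 (UMAG_02549) went from 164 ± 19.7 to 75.6 ± 21.8, clp1 from 247 ± 22.7 to 121 ± 22.3 and the pheromone gene mfa1 (UMAG_02382) from 187 ± 31.5 to 78.8 ± 6.13. The other 7, including pit1, hdp2, bE and bW, did not pass. Camera gave adjusted p = 0.915 and a downward direction, as did the median log2 change of -0.07, whereas the mean was 0.05. The mfa1 call was lost with edgeR (adjusted p = 0.265, in a range of 0.00336 to 0.265), and the hdp1 call with DESeq2 (0.0511, in a range of 0.00464 to 0.0524), while thinning ended the calls of clp1 (0.161) and biz1 (0.378).

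Of the effectors, 4 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone. The falls were rsp3, to 0.444 of its 2 dpi mean, erc1 to 0.585, the effector cce1 (UMAG_12197) to 0.524 and the seedling effector see1 (UMAG_02239) to 0.376 (0.222 without 12 dpi replicate 2). The rises were cmu1 at 1.42-fold and the jasmonate signalling effector jsi1 (UMAG_01236) at 1.74-fold. The 6 that did not pass were pep1, pit2, stp1, tin2, mig1 (UMAG_03223) and apB73 (UMAG_02011), and camera gave adjusted p = 0.363. With edgeR cmu1 (adjusted p = 0.0912) and jsi1 (0.0522) were lost, in ranges of 0.0332 to 0.169 and 0.0135 to 0.196, and each was lost without any of 2 dpi replicates 1 and 2 and 12 dpi replicates 2 and 3 (0.0578 to 0.144 for cmu1, 0.0509 to 0.0961 for jsi1). The see1 call was lost without 2 dpi replicate 1 (0.0656), 2 dpi replicate 2 (0.0572) or 12 dpi replicate 3 (0.0533), and the cce1 call in thinned libraries (0.0644).

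Within the effector cluster ranges, some loci rose and others fell between the stages. In the 19A range 6 of 16 rose and 3 fell, with the same counts adjusted over the list alone. UMAG_05295 went from 6.18 ± 5.43 to 1355 ± 61.2, UMAG_05312 rose 12.3-fold and UMAG_05306 9.01-fold, whereas UMAG_05318 went from 736 ± 162 to 140 ± 87.3. Camera gave adjusted p = 0.0341 and adjusted p = 0.253 with an estimated correlation, and the call was also lost without axenic replicate 1 (0.0591), axenic replicate 3 (0.0559), 12 dpi replicate 2 (0.2) or 12 dpi replicate 3 (0.0732). In the 2A, 6A and 9A ranges 6 of 22 rose and 10 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.25). UMAG_03746 went from 7 reads at 2 dpi, all in replicate 3, to 172 ± 12.8, and UMAG_03747 rose 11.7-fold and UMAG_03749 10.9-fold, while UMAG_02540 fell to 0.12 of its 2 dpi mean. In the mig2 range 2 of 4 rose, and 2 adjusted over the list alone, with UMAG_06179 3.56-fold higher (camera adjusted p = 0.0948, and 0.0313 without 12 dpi replicate 1).

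**Figure D4:**
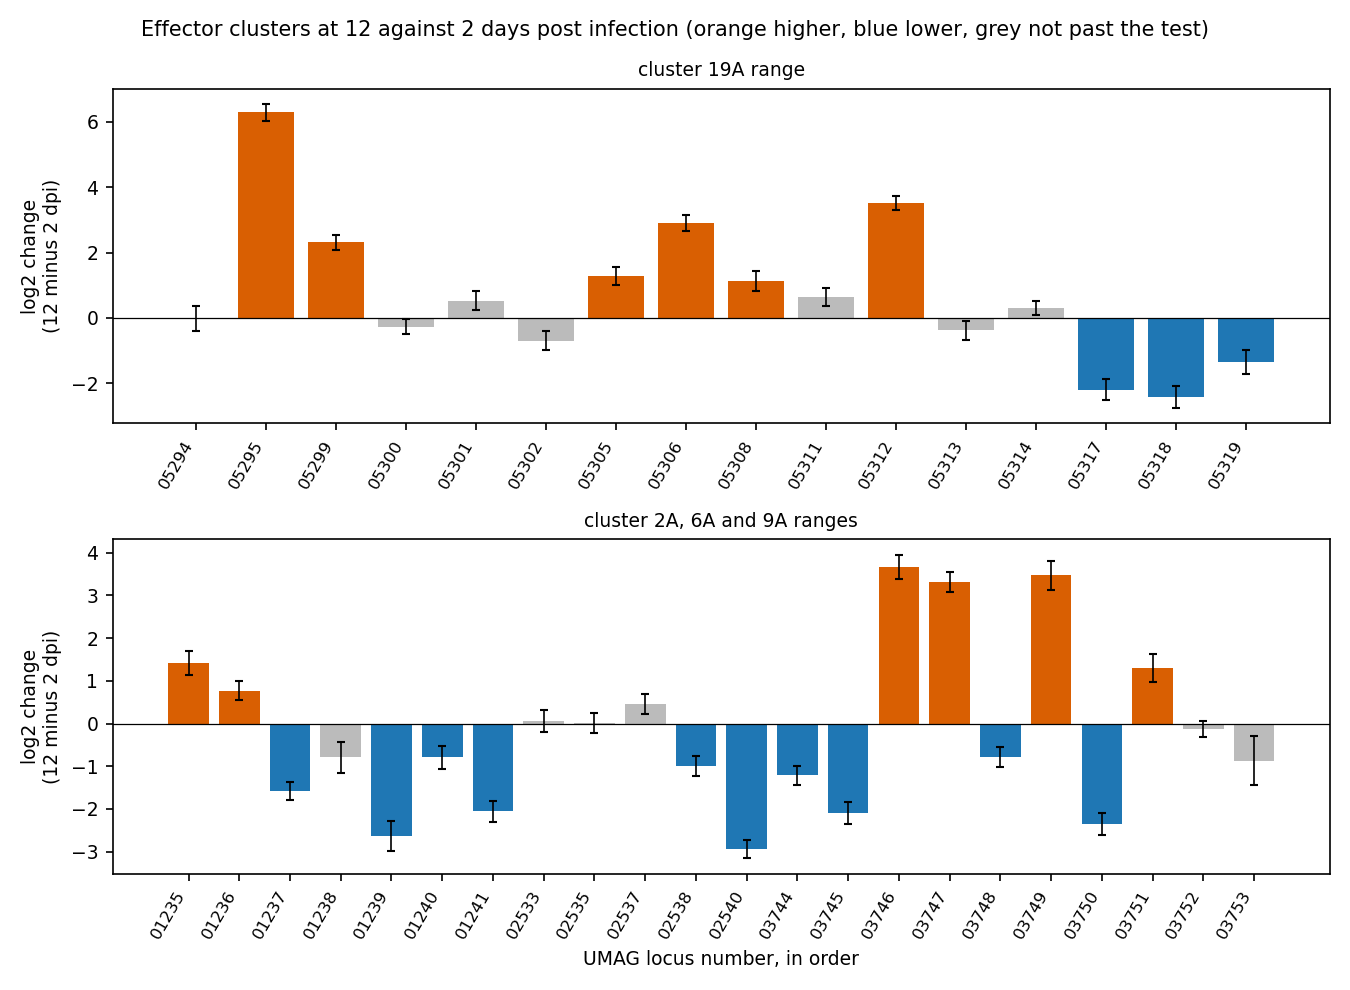
Log2 change of log2(scaled read count + 12) between 12 and 2 dpi for the tested loci of the 19A range (top) and of the 2A, 6A and 9A ranges (bottom), in locus order, with bars at the fitted change, whiskers at the SE and 3 libraries per stage. Bars past the threshold are orange for rises and blue for falls, with 6 risen and 3 fallen in the top panel and 6 risen and 10 fallen in the bottom panel.

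Several iron and nutrient genes differed between the stages. In the iron list 4 of 5 tested genes rose and 1 fell, also adjusted over the list alone, with UMAG_01436 29.2-fold higher, sid2 4.20-fold and UMAG_01435 2.67-fold, and fer1 at 0.23 of its 2 dpi mean (0.0991 without 12 dpi replicate 3). The rise of sid1, 4.38-fold from 9.74 ± 2.55, was lost without 2 dpi replicate 1 (adjusted p = 0.0718), 2 dpi replicate 3 (0.0769) or 12 dpi replicate 2 (0.0577, with a fold of 2.89). Camera gave adjusted p = 0.0083, and adjusted p = 0.0581 with an estimated correlation. Of 3 nutrient genes 2 rose, and 2 adjusted over the list alone, ump2 at 2.79-fold and srt1 at 1.68-fold (camera adjusted p = 0.0176, and adjusted p = 0.0808 with an estimated correlation), and the srt1 call was lost with a weight per group (adjusted p = 0.0562) and in thinned libraries (0.47). The lipid transporter gene mmf1 was 1 of 2 tested genes to rise, also adjusted over the list alone (camera adjusted p = 0.184). Of the chitin synthases 1 rose and 0 did so adjusted over the list alone (camera adjusted p = 0.423). Of the reference genes gapdh and act1 fell, 2 of 3 and also 2 adjusted over the list alone, to 0.664 and 0.585 of their 2 dpi means with the authors' size factors, and both were also lower under 3 other scalings. The gapdh call was lost with edgeR (adjusted p = 0.0518) and without 2 dpi replicate 2 (0.0657), 2 dpi replicate 3 (0.0507) or 12 dpi replicate 3 (0.0512), in a range of 0.00613 to 0.0791. For that list camera gave adjusted p = 0.0643, and 0.0473 without axenic replicate 2 and 0.0223 without 2 dpi replicate 1.

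Across the genome, 1287 genes differed between the stages by limma, 589 higher and 698 lower at 12 dpi. The balance turned in some alternatives, to 471 higher and 418 lower by edgeR with TMM, 454 and 435 by edgeR with size factors and 525 and 473 by DESeq2. The largest rises were UMAG_03046, from 161 ± 144 to 34373 ± 961, UMAG_11002, with 0 reads at 2 dpi and 1653 ± 511 at 12 dpi, at least 624-fold above the level of 3 reads over the 2 dpi group, UMAG_05295 and cyp3. The largest falls were UMAG_10115, from 735 ± 179 to 13.4 ± 19.6, UMAG_02194, from 283 ± 67.7 to 0 reads, UMAG_06223, from 1150 ± 416 to 55.4 ± 46.1, and UMAG_10557, from 454 ± 98.7 to 21.4 ± 9.72. In simulated libraries 9.9% of the limma calls of this comparison were false, against 5% for edgeR and 4.9% for limma with a weight per group, which made 889 and 800 calls here, 861 and 800 of them shared with the 1287. Of 87 calls for named genes and list members in this comparison, edgeR lost 11 and the weight per group 13. Without 2 dpi replicate 1 the number of lower genes was 458, with all libraries thinned it was 350, and 190 genes passed a test against a 2-fold change.

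By time course, 543 genes had risen at both stages without a called difference between them, 176 had risen at both and were higher at 12 dpi, and 132 had risen at both and were lower at 12 dpi. The rise of 227 genes was called at 12 dpi and not at 2 dpi, together with a call between the stages, which included ros1, pks1, pks2, mtt1, ria1 and adi1. With edgeR and with DESeq2 the last 3 were called at 2 dpi as well, so this grouping holds for them by limma only. For mtt1 it does not hold by limma with a pseudocount of 1 either (adjusted p = 0.0175 at 2 dpi). Another 91 genes had risen at 2 dpi, were not called at 12 dpi and were lower at 12 than at 2 dpi, among them UMAG_02194, with 0 reads at 12 dpi.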

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

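The test of the reference genes under other scalings and the depth test were chosen only after the result was seen, and so was the reading of the maize-read test described here. The other tests were fixed before their results were seen.

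For 17 genes the change against axenic culture had opposite directions at the 2 stages, each change and the difference between the stages passing limma's threshold. Of these, 7 were lower at 2 dpi and higher at 12 dpi, such as UMAG_01476 (log2 changes -2.45 ± 0.20 and 0.86 ± 0.20, difference 3.32) and UMAG_05422 (-1.95 ± 0.31 and 1.11 ± 0.31, difference 3.06). The other 10 were higher at 2 dpi and lower at 12 dpi, such as UMAG_11487 (1.06 ± 0.37 and -1.15 ± 0.37, difference -2.21). For these 17 genes only the difference between the stages was followed gene by gene through the alternatives. Whether their changes against culture hold there was not tested.

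The broad rise in infected leaves could come from maize reads counted as fungal, or from the low fungal depth of the infected libraries. With every library thinned to the smallest total, 1297 of the 2125 genes and 1746 of the 2731 were still called, with 0 of opposite sign, which argues against the depth difference as the whole source. Constant plant reads would make the scaled values of risen genes fall with fungal depth, by a log2 ratio of -1.77 at 2 dpi and -1.53 at 12 dpi, and the medians were -0.02 (interquartile range -0.23 to 0.20) and -0.12 (-0.54 to 0.27). That met the bound set beforehand for excluding plant reads, but the bound assumed equal plant reads in every library, while total reads per library are not known and a more deeply sequenced library would carry more of both, so maize reads and fungal expression cannot be told apart by this test for the risen genes as a set. A change of the fungal programme in the plant stays open beside them.

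The 3 reference genes could be lower in leaves because of the authors' scaling of the libraries. Their median change at 12 dpi was at most -1.29 under size-factor, TMM, upper-quartile and total-count scaling, which argues against the choice of scaling as the cause. Whether transcripts per fungal cell changed was not measured, and a biological difference between cultured cells and hyphae in the plant was not tested.

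For each comparison the 6 libraries allow 10 splits into 3 and 3, and 1 of them, the real one, gave as many genes as the real split, which is too few splits for a share under 0.05. By limma on the 2 groups alone the real splits called 2619, 2546 and 1021 genes for 2 dpi against axenic, 12 dpi against axenic and 12 against 2 dpi. The highest other splits called 0, 0 and 0, with 67, 47 and 181 genes at an unadjusted p under 0.05.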

How the results depend on the processing

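TMM-rescaled values, the weight per group, and the overlap and the folds without each library were chosen only after the data were seen. The edgeR test with TMM factors was fixed beforehand as the main test. Its use as an alternative, with limma in its place, was chosen only after the data were seen. No genome-wide call shared with an alternative changed sign, and no named change called in the report or in an alternative reversed, while uncalled changes near 0 crossed it, such as bW between the stages (-0.18 to 0.19). Of the named changes not called by limma, 9 at 2 dpi, 3 at 12 dpi and 7 between the stages were called in at least 1 alternative. Without 1 library the fold moved by more than 1.5 times for 16 of 64 called list or symbol genes with a finite fold at 2 dpi, 17 of 73 at 12 dpi and 10 of 63 between the stages, and by more than 2 times for 4, 5 and 4 of them, such as fer1 (0.214 to 0.0923) at 12 dpi. With the test against a 2-fold change left out of this count, 243 of 281 named calls held in every alternative that tested them. These were 84 of 92 at 2 dpi, 96 of 102 at 12 dpi and 63 of 87 between the stages. Counts moved by more than 1.5 times in these cases, and beyond fewer reads or libraries in the fit the cause was not tested. Thinning gave 1375 genes (650 fallen) at 2 dpi, 1807 (864 fallen) at 12 dpi, 645 (295 risen, 350 fallen) between the stages and 1033 changed alike at both stages. The test against a 2-fold change gave 578 (408 risen, 170 fallen), 921 (559, 362) and 190 (109, 81). Between the stages the weight per group gave 800 (361, 439), and edgeR called 471 risen and 418 fallen with TMM and 454 and 435 with size factors. Of 21 list calls 9 held with an estimated correlation. Leaving out 1 library gave 1661 to 2511 genes at 2 dpi, 2295 to 2781 at 12 dpi and 871 to 1356 between the stages, with 458 (without 2 dpi replicate 1) to 764 (without 12 dpi replicate 2) fallen there, 1312 to 1858 changed alike and 18 to 22 list calls. The replicate block gave 2133, 2717 and 1247 genes and 21 list calls, and no list call changed. Deviations of same-numbered libraries had correlations of -0.076 to 0.173, and those of different-numbered libraries -0.164 to 0.08. Counting error at few reads weakens such correlations, so they cannot decide whether the numbers pair the libraries. Under upper-quartile and total-count scaling the median change of all genes at 12 dpi was -0.27 and -0.23, against -0.09, and at 2 dpi under total-count scaling it was -0.22, against -0.06. The plant-read alternative was not run for lack of product text, and the mannosylerythritol lipid list could not be tested where a left-out library took it below 2 members. Without the filter 6707 genes were tested and 2953 were called at 12 dpi, 2653 of them shared with the 2731. With a median gene at 3 to 10 reads at 12 dpi, genes below the filter were compared there on few reads in the leaf.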

Other observations

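The genes and tests of the next paragraph were chosen only after the data were examined, though from the symbols of the reference table and not from their values, and the tests of neighbouring genes were fixed before their results were seen, apart from the shuffle for pairs at least 1000 bases apart, which was chosen only after the result was seen.

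The endoglucanase genes, for enzymes that cut cellulose, rose at both stages and were lower at 12 than at 2 dpi in all 3 cases. Means of egl1 (UMAG_06332) went from 0.753 ± 0.343 in culture to 8468 ± 1322 at 2 dpi and 1930 ± 41.2 at 12 dpi (log2 changes 9.36 ± 0.15 and 7.25 ± 0.15 against culture). The gene egl3 (UMAG_04816) reached 2406 ± 273 and then 274 ± 72.4, and egl2 (UMAG_02523) 2800 ± 573 and 1635 ± 255, where the later fall was lost without 2 dpi replicate 1 (adjusted p = 0.0593, in a range of 0.00435 to 0.0773). Of 6 opt genes, which carry the symbol of oligopeptide transporters, 4 rose at both stages, including opt4 (UMAG_02387), from 0.210 ± 0.0880 to 194 ± 12.3 and 302 ± 57.0, and opt3 (UMAG_05968), from 3.33 ± 0.781 to 279 ± 171 and 218 ± 85.5. The call of opt1 (UMAG_10908), another of the 4, was lost at 2 dpi without 2 dpi replicate 3 (adjusted p = 0.0533), and at 12 dpi without axenic replicate 1 (0.0672), axenic replicate 2 (0.0849) or 12 dpi replicate 2 (0.0931) and in thinned libraries (0.112). The gene opt6 (UMAG_04347) fell from 152 ± 20.5 to 73.3 ± 5.96 at 2 dpi, a call lost without axenic replicate 3 (adjusted p = 0.0503) and in thinned libraries (0.158), and was 2.84-fold higher at 12 than at 2 dpi, where it did not differ from culture by the threshold (adjusted p = 0.276). The gene afu3 (UMAG_04309) rose from 0.571 ± 0.0636 to 797 ± 207 and 449 ± 164, and dur3-1 (UMAG_02625), with the symbol of urea transporters, from 1 axenic read to 176 ± 27.5 and 91.2 ± 45.8.

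Genes that rose at 12 dpi often lay next to each other. Among 5351 neighbouring pairs of tested genes 423 held 2 risen genes, against a mean of 299.7 and a maximum of 340 in 1000 shuffles of the gene order (permutation p = 0.001, the smallest these shuffles can give). The listed effector clusters and other listed genes could produce this. Without all listed genes, however, the ratio of observed to shuffled pairs was 1.35 (362 against 268.4, permutation p = 0.001). Effector clusters outside the lists were not left out. Reads shared by abutting genes could as well, but for pairs at least 1000 bases apart the ratio was 1.35 when genes were shuffled only among those with as many such gaps beside them (238 against 176.7, permutation p = 0.001), and 1.73 when all genes were shuffled, which counts risen genes lying beside wide gaps as pairing. Each ratio of 1.35 argues against its own cause as the whole source when taken alone. With listed genes and close pairs both left out, the ratio was 1.74 (215 against 123.4) when all genes were shuffled, which has the same limit. Both causes acting together were not tested with the narrower shuffle. Effector clusters outside the lists, and reads shared by tandem copies outside the lists, were not tested. They stay open beside a shared regulation of neighbours, which was not tested either.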
